A study of Drosophila melanogaster with 12 samples.

How the data were processed

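RNA of whole male Drosophila melanogaster was measured on 12 Affymetrix Drosophila Genome 2.0 arrays, each from 8 pooled flies. The titles of the samples gave 4 groups of 3 arrays: males exposed to sucrose, males exposed to methylphenidate, F1 males of 2 sucrose-exposed parents, and F1 males of a sucrose-exposed father and a methylphenidate-exposed mother. Per the submitters' processing notes, RMA, affy and limma were used. Their versions, order and settings are not given in the sources used here.

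The deposited values are log2 signals, 1 per probe set and array, as processed by the authors. Whether and how background was corrected is not stated, and the settings of any normalization are not given. The log base was not stated, so it was checked on the bacterial hybridization controls: from BioB to Cre their signal rose by 5.72, against 6.06 for the log2 of the nominal concentration ratio, a ratio of 0.944. Natural logs would have given a ratio of 1.36. Values lay close to a floor near 0 for a large part of the array: between 36.8% and 38.8% of probe sets had a value under 0.5 on each array, and fold changes of such dim probe sets are understated.

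Of 18952 probe sets, 183 controls were left out and 18769 were tested, without a filter on dim probe sets. Gene names came from the array's annotation: 13647 tested probe sets had 1 gene, 402 had several and 4720 were unnamed here. Symbols of 13544 of the single-gene probe sets were updated through gene identifiers of the RefSeq annotation, which was used for names only. The named probe sets covered 11983 genes. Probe sets with several genes were never named. For gene lists, each gene was represented by its probe set with the highest mean over the 12 arrays.

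All 12 arrays entered 1 fit of 4 group means with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). The contrasts were methylphenidate minus sucrose in exposed males, methylphenidate-exposed mother minus sucrose-exposed parents in F1 males, and the difference of these effects (F1 minus exposed). The last was F1 males of sucrose-exposed parents minus males exposed to sucrose, called the sucrose groups below. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over the 18769 probe sets, and all tests were two-sided. Errors of log2 changes are standard errors (SE) of this fit. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

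The samples, tests, gene lists and naming rule described here were fixed before the data were examined. In the exposed-male and F1 contrasts, the named genes were the 12 largest increases and the 12 largest decreases among single-gene probe sets past the threshold whose 3 and 3 values did not overlap. Where fewer than 24 qualified, the genes with the smallest unadjusted p filled the list. The other contrasts had 6 in each direction, nothing filled up. From each gene list, up to 4 members with the smallest p were named, and the dopamine genes DAT, ple, Ddc and Vmat always. Other genes named are said to have been chosen after their values were seen.

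Of 27 gene lists, 26 had at least 5 measured genes and were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Names that matched no single-gene probe set were left out of a list. List members past the threshold were counted over all probe sets and adjusted over the list alone. Correlations of log2 changes across probe sets were set against 100 pairs of splits of the 6 arrays of each generation. Where contrasts shared the sucrose-exposed arrays, 100 draws without effects were simulated, with normal noise independent between probe sets. Array measures were compared between groups by exact permutation tests, whose smallest two-sided p for 3 against 3 arrays is 0.1.

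The fit was tested on simulated data with 200 of 18769 probe sets changed. Each probe set had its real mean and its spread as moderated by limma, with independent normal noise. Recovery in the real data can be lower. Log2 changes of 1 and 2 were recovered in 100% of cases in each of the 4 contrasts. A log2 change of 0.5 was recovered in 77.6% of cases in exposed males, 76.1% in F1 males, 76.1% between generations and 29.9% for the difference of effects.

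The alternatives fixed before the data were examined were a fit of the groups of the contrast alone, the replicate number as a block, leaving out the dimmest 30% or 50% of probe sets, quantile normalization of the deposited values, centring of each array on its median, eBayes with trend and robust settings, array weights, 1 probe set per gene, the mean of a gene's probe sets, and leaving out each array in turn. A fit with the 3′ minus 5′ difference of the GAPDH control probe sets as a covariate was added after the data had been seen, as were a fit of the F1 arrays alone for the width of its intervals and a split of the sucrose-fed arrays, 1 against 2, between the contrasts that share them.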

Results

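The series addressed how male flies respond to methylphenidate, a psychostimulant that blocks the dopamine transporter, and whether sons of drug-exposed mothers differ from sons of control mothers. Exposed males had received methylphenidate or sucrose for 24 hours. F1 males came from parents that were both exposed to sucrose, or from a sucrose-exposed father and a methylphenidate-exposed mother; the time of parental exposure is not given in the sources used here. The series summary names 1 cross, with drug-exposed mothers, for all 6 F1 samples; the sample labels, which name 2 crosses, were followed, and the F1, difference and generation contrasts rest on them. Each group had 3 arrays of 8 whole flies. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, and the number of arrays limits the precision. Arrays of a group correlated at 0.995 to 0.997. The median signal was 1.49 to 1.57 on 11 arrays and 1.37 on replicate 3 of the F1 males of sucrose parents.

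In males fed methylphenidate, genes of detoxification enzymes rose. GstD2, a glutathione S-transferase, had a log2 signal of 7.29 ± 0.726 (SD, n = 3) with the drug against 1.23 ± 0.278 (SD, n = 3) with sucrose, a 66.7-fold difference (log2 6.06 ± 0.31 SE, limma adjusted p = 4.9e-08). The cytochrome P450 genes Cyp6a8 (39.0-fold), Cyp6w1 (13.5-fold), Cyp6a2 (11.4-fold), Cyp12d1-d (11.1-fold), Cyp6a14 (10.8-fold) and Cyp28a5 (9.65-fold) rose, as did Ugt37A2, a UDP-glycosyltransferase (18.6-fold). The other large increases were in CG13659 (23.1-fold), CG11893 (17.6-fold) and CG6908 (14.8-fold), which belong to the ecdysteroid kinase-like family, and in CG2065 (17.6-fold), a short-chain dehydrogenase.

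**Figure D1:**
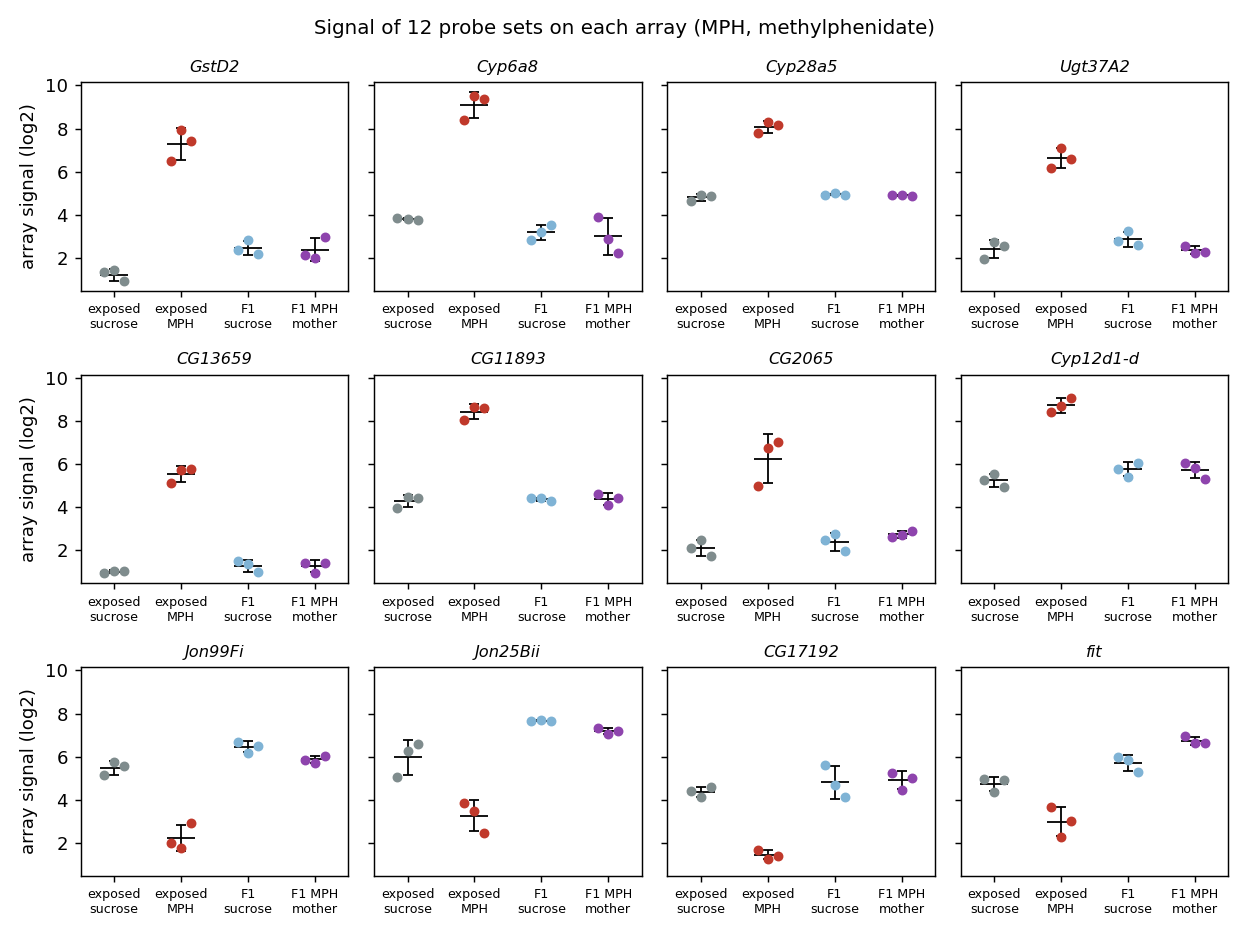
Log2 signal of 12 probe sets on each of the 12 arrays, by group; points are arrays, horizontal bars group means and whiskers SD (n = 3). GstD2 averaged 7.29 in methylphenidate-fed males and 1.23 to 2.45 in the other groups, and Jon99Fi averaged 2.23 against 5.49 to 6.46.

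The lists of these enzyme families moved with them. Of 86 P450 genes 26 rose and 2 fell (31 and 3 adjusted over the list alone), with Cyp9b2 at 6.41-fold and Cyp4e2 at 3.92-fold beside those above. Of 37 glutathione S-transferases 17 rose and none fell (20 and 1 adjusted over the list alone), among them GstE3 (3.65-fold), GstD10 (3.78-fold) and GstD1 (2.51-fold). Of 35 UDP-glycosyltransferases 11 rose and none fell (14 and 1 adjusted over the list alone), including Ugt35C1 (7.59-fold). Camera called each of these 3 lists (adjusted p = 1.8e-16, 1.6e-17 and 1.6e-11), and they were the lists that passed in this contrast with an estimated correlation as well (adjusted p = 0.0104, 0.0103 and 0.0121 with an estimated correlation).

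Digestive genes moved in opposite directions. The largest decreases included the serine peptidases Jon99Fi (9.59-fold lower), Jon25Bii (6.49-fold lower), Jon65Ai (3.69-fold lower) and Jon25Bi (3.52-fold lower), the carboxypeptidase CG12374 (5.42-fold lower) and the lipases CG17192 (7.51-fold lower) and CG6295 (2.95-fold lower). Of 39 digestive genes 11 rose and 12 fell (17 and 16 adjusted over the list alone). The list's median log2 change was 0.08 and its mean -0.13, and camera gave the direction up without passing (adjusted p = 0.857). Divided after its values were seen, the list held 14 carbohydrases, of which 10 rose and none fell, for example the maltase Mal-B1 (5.88-fold), and 22 peptidases, of which 1 rose and 11 fell, for example epsilonTry (2.89-fold lower).

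Genes of nutrient signalling moved both ways. Those with the smallest p fell: AkhR, the receptor of adipokinetic hormone, fell by 1.05 ± 0.11 (SE) on the log2 scale, the perilipin Lsd-1 fell by 0.81 ± 0.11, the sugar-responsive transcription factor sug fell by 0.99 ± 0.14 and fit, a secreted fat body peptide, fell by 1.76 ± 0.27 (limma adjusted p = 5.4e-05, 0.000527, 0.00093 and 0.00133). Of the 41 genes of the insulin, adipokinetic hormone and storage list 3 rose and 5 fell (6 and 6 adjusted over the list alone), and camera did not call it (adjusted p = 0.841). Of 34 neuropeptide genes 2 fell, CCHa2 by 0.93 and ETH by 0.52 on the log2 scale (2 adjusted over the list alone; camera adjusted p = 0.357). The remaining large decreases were phu (8.41-fold lower, from 3.21 to 0.14, near the floor), CG3348 (3.40-fold lower), CG15155 (3.17-fold lower) and CG13912 (3.07-fold lower).

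Further lists shifted as a whole by camera, but not with an estimated correlation. Of 30 antioxidant genes 10 rose and 1 fell (12 and 2 adjusted over the list alone), among them Keap1 (2.59-fold), Gtpx (1.53-fold), Prx3 (1.42-fold) and Trxr1 (1.40-fold), with adjusted p = 2.2e-05, and adjusted p = 0.121 with an estimated correlation. Of 33 ecdysone and juvenile hormone genes 5 rose and none fell (5 and 0 adjusted over the list alone; adjusted p = 0.00747, and 0.364 as the adjusted p with an estimated correlation). They included Jheh2, a juvenile hormone epoxide hydrolase (3.85-fold), and JhI-26 (1.57-fold), but also Cth, a cystathionine gamma-lyase (2.10-fold), and MsrA, a methionine sulfoxide reductase (1.99-fold). None of 42 ribosomal protein genes passed over all probe sets, with 18 higher and 1 lower adjusted over the list alone, a median log2 change of 0.16 and adjusted p = 1.6e-09 (adjusted p = 0.364 with an estimated correlation). Of 13 heat shock genes Hsp60A and Hsc70-4 rose (3 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00189, and adjusted p = 0.364 with an estimated correlation. This list lacks 14 of its names, among them Hsp22, Hsp23, Hsp83 and the Hsp70 genes.

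The list of 30 antimicrobial peptide and immune genes was called up by camera (adjusted p = 0.0196, and adjusted p = 0.705 with an estimated correlation). The peptidoglycan amidase PGRP-LB was higher by 0.84 and PGRP-SC2 lower, at -0.96, on the log2 scale (1 and 1 adjusted over the list alone). The immune list lacks 12 of its names, among them DptA, AttA, AttB, AttC, CecA1, CecA2, CecC and Dro. Of 15 fat body genes Sodh1 (2.53-fold) and NLaz (1.45-fold) rose and Obp99b fell by 0.93 on the log2 scale (3 and 1 adjusted over the list alone; adjusted p = 0.00189, and adjusted p = 0.521 with an estimated correlation). Lists called down were the 56 testis genes (1 lower, w-cup, and 9 adjusted over the list alone; median log2 change -0.18, adjusted p = 3.5e-07), the 50 seminal fluid genes (none past either adjustment, adjusted p = 0.000324), the 23 muscle genes (none past either adjustment, adjusted p = 0.000139) and the 38 neuron and synapse genes (Rim lower, 1 adjusted over the list alone, adjusted p = 0.0028). With an estimated correlation these gave adjusted p = 0.521, 0.585, 0.585 and 0.612.

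None of the 4 dopamine genes named beforehand passed the threshold. DAT, the dopamine transporter, differed by 0.10 ± 0.11 (SE) on the log2 scale, the tyrosine hydroxylase gene ple by -0.08 ± 0.08, Ddc by -0.07 ± 0.10 and the vesicular transporter Vmat by -0.14 ± 0.09 (limma adjusted p = 0.783, 0.713, 0.838 and 0.530). None of the 34 biogenic amine genes measured (Dop1R2, Oamb, Trh, Hn and b had no probe set under their name) passed in limma over all probe sets or adjusted over the list alone, and camera did not call the list (adjusted p = 0.915). The signal of ple lay at the floor (0.15 with sucrose).

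Over the array, 629 of 18769 probe sets passed in exposed males, 447 higher (391 genes) and 182 lower (166 genes), of which 102 and 23 changed over 2-fold; 2872 had an unadjusted p under 0.05. The 3 and 3 values did not overlap for 627 of the 629, and for 21.2% of all probe sets, where chance gives 10%. With quantile normalization the split was 479 higher and 347 lower, so the share of increases was 58.0% in place of 71.1%. Over all alternatives the share ran from 56.9%, with trend and robust settings, to 80.2%. The latter came without replicate 3 of the sucrose-fed males (319 higher, 79 lower). The 3′ minus 5′ difference of the GAPDH controls is a measure of RNA integrity. It was 1.62 ± 0.086 in sucrose-fed and 1.504 ± 0.003 in methylphenidate-fed males (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). With it as a covariate 203 probe sets passed, 197 of them among the 629. All 24 named genes were kept, but they were chosen for large changes and do not speak for the other calls. The count was 411 with only these 6 arrays, 1009 with trend and robust settings, 404 without replicate 1 and 398 without replicate 3 of the sucrose-fed males.

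**Figure D2:**
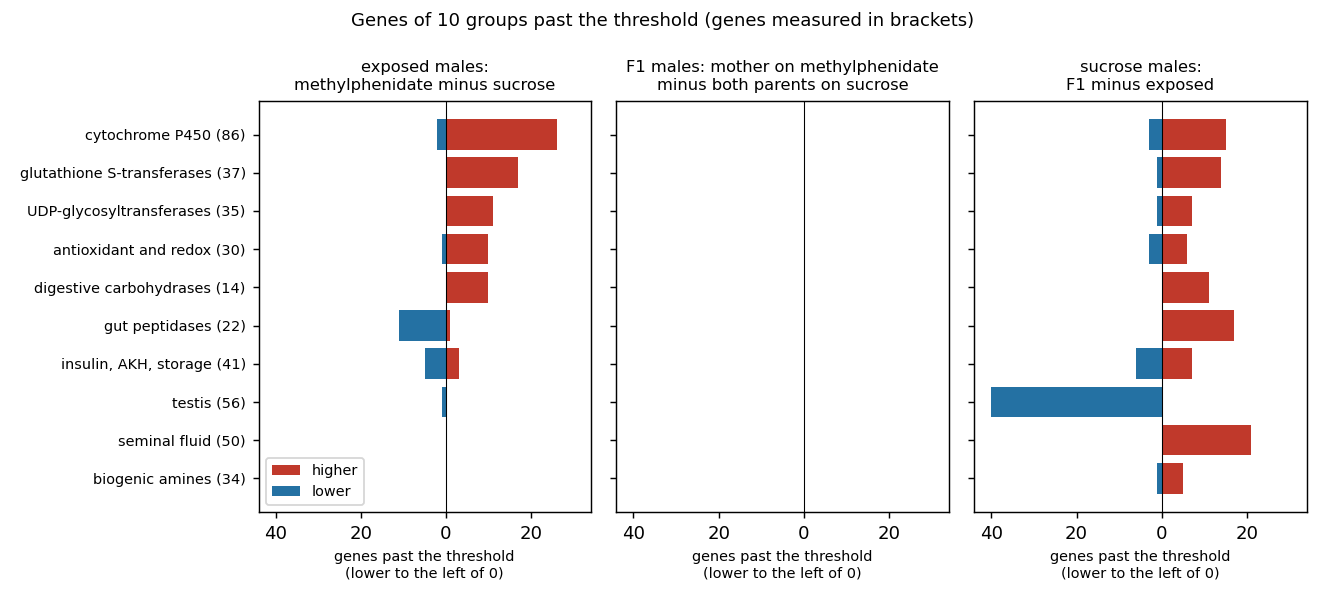
Genes past the threshold in 10 gene groups for 3 contrasts; bars to the right count higher genes and bars to the left lower genes, with the number of genes measured in brackets. In exposed males 26 of 86 P450 genes were higher, in F1 males no gene of these groups passed, and between the sucrose groups 40 of 56 testis genes were lower in F1 males.

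Between sons of methylphenidate-exposed mothers and sons of sucrose-exposed parents, little passed the threshold. The largest log2 changes, 1.84 and -1.84, did not pass. A single probe set passed, which is unnamed here and was higher in all 3 sons' samples of exposed mothers (1.42 ± 0.191 against 0.45 ± 0.116, SD, n = 3 each; log2 change 0.96 ± 0.12 SE, limma adjusted p = 0.0219). No named gene passed. The smallest p-values belonged to CG13912 (log2 change 0.72 ± 0.11 SE) and CG12780 (-0.94 ± 0.14), both with limma adjusted p = 0.0581, to CG16775 (-1.18 ± 0.19, adjusted p = 0.078), and to Cyp4ad1 (0.60 ± 0.10) and CG42822 (0.84 ± 0.14), both with adjusted p = 0.0806.

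The other genes that filled the naming rule did not pass either. CenB1A, CG12402, Ctr1C, CG4250, CG17598, muskelin, mub, the lipid droplet gene Jabba, CG34165, CG13743, CG8490, Prp6, CG31606, loaf and vret had positive changes between 0.36 (Ctr1C) and 0.89 (CG4250). Negative changes were measured for CG15255 (-0.68), the clock gene cyc (-0.44), Muc68E (-0.65) and CG15818 (-0.49). Their limma adjusted p lay between 0.169 and 0.275. DAT differed by 0.08 ± 0.11 (SE), ple by 0.01 ± 0.08, Ddc by 0.15 ± 0.10 and Vmat by 0.20 ± 0.09, none past the threshold (limma adjusted p = 0.904, 0.983, 0.733 and 0.619). None of the 34 biogenic amine genes passed over all probe sets or adjusted over the list alone.

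No member of any of the 26 lists passed over all probe sets in limma. Camera called the digestive list (39 genes, median -0.17, adjusted p = 4.1e-07) and the immune list (30 genes, median -0.21, adjusted p = 2.2e-06) down, and the neuron (38 genes, median 0.16, adjusted p = 2.2e-06), muscle (23 genes, median 0.11, adjusted p = 0.0231) and heat shock lists (13 genes, median 0.11, adjusted p = 0.0231) up. All 5 were lost with an estimated correlation (adjusted p = 0.882 with an estimated correlation for each), and fry called none in a direction. Its test of mixed directions passed for 5 lists: clock (adjusted p = 0.000301), heat shock and activity-regulated (0.00476 each), neuron (0.0197) and nutrient genes (0.0320). Adjusted over the list alone, 1 neuron gene and 1 heat shock gene were higher, and none of the digestive, immune and muscle genes passed. In other lists 4 nutrient genes (AkhR, Lsd-1, fit and sug), 3 clock, 3 activity-regulated, 2 fat body, 2 P450, 1 neuropeptide and 1 ecdysone list gene were higher, and 1 clock gene and 1 P450 gene lower, by that adjustment.

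The genes that responded in exposed males did not change alike in F1 males. By limma, 82 of the 629 probe sets had an unadjusted p under 0.05 in F1 males, as had 1513 of all 18769. None of the 629 passed, and 38.2% of them had the sign of the exposed-male change. Their median change in F1 males, signed as in exposed males, was -0.04 against 0.56 in exposed males. In a fit of the F1 arrays alone, added after the data had been seen, the 95% interval excluded 0.5 times the exposed-male change for 483 of them (76.8%), and for 123 of the 125 that had changed over 2-fold. GstD2 differed by -0.07 ± 0.31 (SE) and Cyp28a5 by -0.05 in F1 males.

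**Figure D3:**
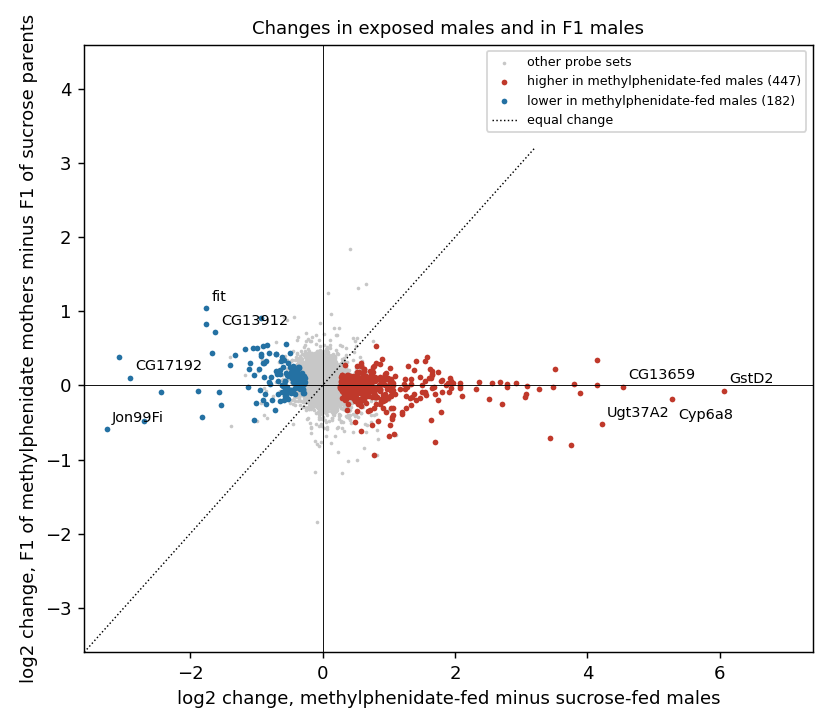
Log2 change in F1 males (mother on methylphenidate minus sucrose parents, vertical) against log2 change in exposed males (methylphenidate minus sucrose, horizontal) for 18769 probe sets; red and blue points passed in exposed males (447 higher, 182 lower) and the dotted line marks equal change. The coloured points spread along the horizontal axis, with GstD2 at 6.06 and -0.07.

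Over the array 1513 probe sets (8.06%) had an unadjusted p under 0.05 in this contrast, where chance gives a share of 0.05. Values did not overlap for 11.5% of probe sets, where chance gives 10%. The count of 1 went to 0 with array weights, under the 50% filter and in gene-level fits (the last 2 leave out this dim, unnamed probe set by construction), to 0 without replicate 2 of the sons of sucrose parents or replicates 2 or 3 of the sons of exposed mothers, and at most to 5, with trend and robust settings. With the replicate number as a block 1 probe set passed, which was another one and lower.

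The effect of methylphenidate was tested for a difference between the generations directly. It differed for 393 probe sets, with F1 effects lower for 267 and higher for 126 (259 and 279 without replicate 1 of the sons of sucrose parents, 330 and 286 with trend and robust settings); 2970 had an unadjusted p under 0.05. Of the 393, 315 had passed in exposed males and 77 in neither generation. The largest differences were those of GstD2 (-6.13 ± 0.44 SE), Cyp6a8 (-5.47 ± 0.49), Ugt37A2 (-4.73 ± 0.33), Cyp6w1 (-4.56 ± 0.29), CG13659 (-4.55 ± 0.24) and Cyp6a14 (-4.13 ± 0.59) on one side and phu (3.45 ± 0.30, with a signal of 0.36, at the floor, in sons of sucrose parents, so that no decrease could be seen in F1 males), CG17192 (3.01 ± 0.41), fit (2.80 ± 0.38), Jon99Fi (2.68 ± 0.34), CG3348 (2.60 ± 0.39) and CG12374 (2.36 ± 0.27) on the other.

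Of the detoxification lists, 23 P450 genes had a lower and 3 a higher effect in F1 males (28 and 5 adjusted over the list alone), 11 glutathione S-transferases a lower one (18 and 2 higher adjusted over the list alone), and 11 UDP-glycosyltransferases a lower and 1 a higher one (13 and 1 adjusted over the list alone). These 3 passed by camera with the preset and with an estimated correlation (adjusted p = 0.0167, 0.0167 and 0.0177 with an estimated correlation). Of the nutrient genes AkhR (1.55 ± 0.16), Lsd-1 (1.24 ± 0.16), fit and sug (1.497 ± 0.204) had higher effects in F1 males. The count was 209 with the GAPDH covariate, 616 with trend and robust settings, 258 without replicate 3 of the sucrose-fed males, 260 without replicate 2 of the sons of sucrose parents, and 244 and 241 without replicates 2 and 3 of the sons of exposed mothers.

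Across all probe sets, the changes in F1 and exposed males, which share no arrays, had a Pearson r of -0.156 and a Spearman rho of -0.164. Probe sets are not independent replicates. Of 100 pairs of splits of the 6 arrays of each generation, 7 gave an absolute r as large, the real one included (permutation p = 0.07), and the highest other was 0.247. Without replicate 1 of the sons of exposed mothers r was -0.195 (permutation p = 0.03, against 0.03 to 0.18 over all the alternatives).

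Without any drug, F1 males of sucrose-exposed parents and males exposed to sucrose differed widely. The labels give the treatment of the parents of the F1 males and not their own. A difference in food, age or handling between these groups cannot be told apart from the generation. Digestive genes were higher in F1 males: 31 of 39 passed and none was lower (33 and 0 adjusted over the list alone), among them the maltases Mal-A4 (4.41-fold) and Mal-A2 (1.996-fold) and the peptidase Jon25Biii (2.36-fold). Fbp2, a fat body protein, was 7.07-fold higher (log2 2.82 ± 0.45 SE, limma adjusted p = 0.00115), and the cuticle genes Acp65Aa (6.46-fold) and Cpr92F (6.41-fold), LManIII, a lysosomal mannosidase (6.07-fold), CG12998 (5.77-fold) and CG15533 (5.30-fold) followed. The largest decreases in F1 males were phu (7.24-fold lower, to 0.36, at the floor), sug (4.02-fold lower), CG3348 (3.31-fold lower), CG13912 (3.04-fold lower), Jabba (2.24-fold lower) and CG1648 (2.18-fold lower).

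Testis genes were lower and seminal fluid genes higher in F1 males. Of 56 testis genes 40 were lower and none higher (47 and 0 adjusted over the list alone), with Mst77F at -0.52 ± 0.07 and w-cup at -0.43 ± 0.07 (log2, SE). Of 50 seminal fluid genes 21 were higher and none lower (23 and 0 adjusted over the list alone), with Spn77Bb at 0.84 ± 0.13 and Sfp38D at 0.52 ± 0.07. Of 115 cuticle genes 21 were higher and 3 lower, of 15 fat body genes 7 and 0, of 23 muscle genes 10 and 0, of 30 immune genes 7 and 0, and of 38 neuron genes 0 and 10 (21 and 3, 8 and 0, 13 and 1, 7 and 0, and 0 and 12 adjusted over the list alone). Detoxification genes were higher too: 15 P450 genes against 3 lower, 14 glutathione S-transferases against 1, 7 UDP-glycosyltransferases against 1, and 6 antioxidant genes against 3 (15 and 3, 16 and 1, 7 and 1, and 10 and 4 adjusted over the list alone). Of 41 nutrient genes 7 were higher and 6 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.399), with AkhR at -0.9996 ± 0.11 and Lsd-1 at -0.88 ± 0.11; the list's median was 0.004 and its mean -0.05, with the camera direction up.

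Camera called 13 lists in this contrast, from the digestive list (adjusted p = 5.3e-23) to the antioxidant list (adjusted p = 0.00688), and none held with an estimated correlation, where the lowest was that of the glutathione S-transferases (adjusted p = 0.153 with an estimated correlation). The values for the digestive, testis and seminal fluid lists were adjusted p = 0.176, 0.284 and 0.259 with an estimated correlation. The other called lists gave adjusted p = 0.259 (P450, UDP-glycosyltransferases, cuticle and fat body), 0.284 (antioxidant), 0.501 (immune and muscle), 0.518 (oxidative phosphorylation) and 0.541 (neuron) with an estimated correlation.

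In all, 3854 probe sets passed, 1188 higher and 2666 lower in F1 males, of which 135 and 8 over 2-fold; 5741 had an unadjusted p under 0.05. The values did not overlap for 32.9% of probe sets, where chance gives 10%. The share of higher calls was 30.8%, and it was 42.7% with quantile normalization (1557 higher, 2091 lower) and 49.4% with arrays centred on their medians (1740 higher, 1779 lower). Without replicate 3 of the sons of sucrose parents it was 40.2% (1159 higher, 1725 lower). The signal of the BioB hybridization control, which does not come from the flies, was 3.89 to 4.15 on the 6 exposed arrays and 4.25 to 4.42 on the 6 F1 arrays (exact permutation p = 0.00216), so the processing of the arrays and the generation cannot be told apart. The GAPDH difference was 1.54 ± 0.044 (SD, n = 3) in these F1 males against 1.62 ± 0.086 in the exposed ones (exact permutation p = 0.3).

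The contrast between the sucrose groups and the methylphenidate contrast share the 3 arrays of sucrose-fed males. Of the 447 probe sets higher with methylphenidate, 252 were also higher in F1 males on this comparison and 3 lower, where independent lists would share 28.3. Of the 182 lower ones, 107 were also lower and 29 higher, where independent lists would share 25.9. The covariance of both sets of changes was 0.0250. In 100 simulated draws without effects its mean was 0.00570 and its highest value 0.00661. The noise of these draws was independent between probe sets, so deviations shared by many genes could exceed that value. Pearson r was 0.381 against a simulated 0.5004, and 66.2% of probe sets had the same sign in both against a simulated 66.7%. Split 1 against 2 after the data had been seen, so that the contrasts shared no array, the sucrose-fed arrays gave covariances of 0.0123 to 0.0246 (mean 0.0194 over 6 splits). These splits leave 1 contrast with a single sucrose-fed array, and no tests were run on them, so part of the excess of shared calls over independent lists may come from the shared arrays. Without replicate 1, 2 or 3 of them 156, 218 or 168 probe sets were higher and 41, 67 or 36 lower in both, of 404, 467 or 398 that passed with methylphenidate, and r was 0.363, 0.450 or 0.400. With the GAPDH covariate 69 were higher and 23 lower in both, of 203. Among the 102 probe sets raised over 2-fold by methylphenidate the median was 1.63 in that contrast and 0.44 between the sucrose groups, with 47 higher and 0 lower. The 23 lowered over 2-fold went both ways between the sucrose groups, 10 higher and 6 lower (medians -1.56 and 0.35): CG3348 (-1.77 and -1.73) and CG13912 (-1.62 and -1.60) were lower in both contrasts, while Jon99Fi and Jon25Bii were higher in F1 males (0.97 and 1.70).

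**Figure D4:**
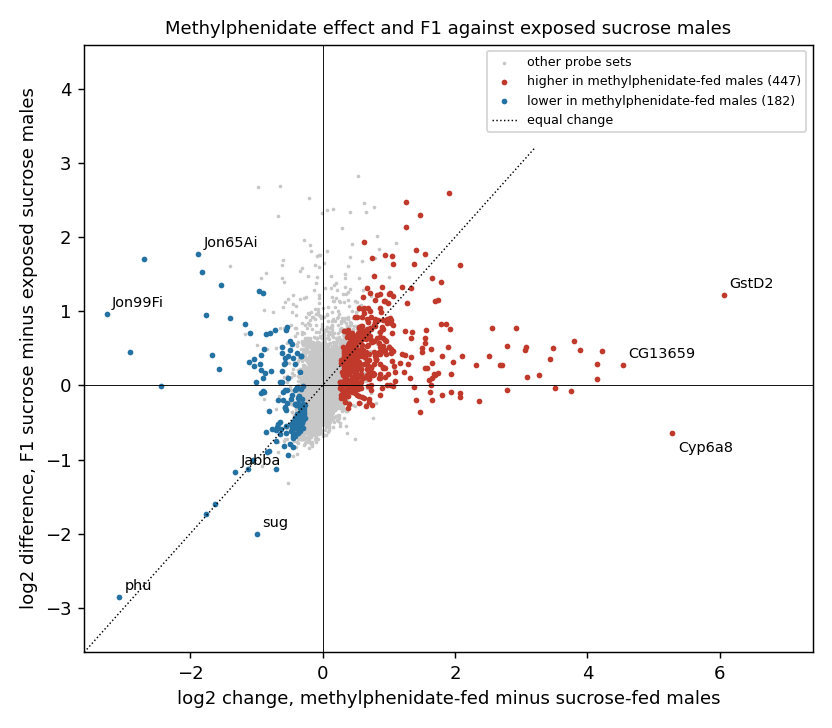
Log2 difference between F1 males of sucrose parents and sucrose-fed males (vertical) against log2 change with methylphenidate in exposed males (horizontal) for 18769 probe sets. Both contrasts use the same 3 arrays of sucrose-fed males, and the dotted line marks equal change. Of 447 red points 252 were also higher in F1 males, and GstD2 lies far below the line (6.06 and 1.22). The position of phu (-3.07 and -2.86) is set by the floor, which it reached in both groups.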

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

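The setting of the F1 intervals against 0.5 times the exposed-male change, the fit of the F1 arrays alone, the split of the sucrose-fed arrays and the GAPDH covariate fit were chosen after the data had been seen. The methylphenidate effect differed between exposed males and F1 males for 393 probe sets in limma. Of 100 relabelings of both generations, 2 called as many, the real one included; the highest other called 611 and kept the arrays of the exposed males as they were. Of the 11 relabelings that kept this split 2 reached the real count, the real one included. Of the others none did, with 0 calls at most, so the count rests on the split of the exposed males.

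Among named genes, the difference (F1 effect minus exposed effect, log2) passed the threshold for the largest increases and decreases of the exposed-male contrast, except Jon25Bi (1.39, limma adjusted p = 0.0997). These genes were chosen for large exposed-male changes, which enter the difference, so the choice favoured its passing. The values below give the size of the difference and are no separate evidence. The difference is listed by its sign. It was negative for GstD2 (-6.13), Cyp6a8 (-5.47), Ugt37A2 (-4.73), Cyp6w1 (-4.56), CG13659 (-4.55), Cyp6a14 (-4.13), CG11893 (-4.13), CG6908 (-3.98), CG2065 (-3.80), Cyp12d1-d (-3.50), Cyp28a5 (-3.32) and Cyp6a2 (-3.29). It was positive for phu (3.45), CG17192 (3.01), fit (2.80), Jon99Fi (2.68), CG3348 (2.60), CG12374 (2.36), CG13912 (2.34), Jon25Bii (2.23), CG15155 (2.11), Jon65Ai (1.81) and CG6295 (1.48).

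Of the genes named for the F1 contrast, none of which passed there, the difference is given where it passed the threshold. These genes were chosen for their small p in F1 males, and the same F1 change enters the difference. The choice therefore favoured a large difference, and its passing is no separate evidence. It was positive for CG4250 (1.42), Jabba (1.39), CG13743 (1.01), CG42822 (0.89), CG31606 (0.78), Cyp4ad1 (0.77), CenB1A (0.67), CG8490 (0.62), mub (0.51) and Ctr1C (0.50). It was negative for Muc68E (-1.73), CG12780 (-1.72), CG16775 (-1.47), CG15818 (-0.99), CG15255 (-0.74) and cyc (-0.58).

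Against all other genes, the mean difference of effects was -0.69 for the glutathione S-transferases, -0.68 for the UDP-glycosyltransferases and -0.66 for the P450 genes. It was -0.47 for the immune list, -0.19 for the ecdysone and juvenile hormone list, -0.17 for the ribosomal proteins, -0.15 for the antioxidant list and -0.0454 for the digestive list. It was 0.27 for the muscle list, 0.22 for the neuron list, 0.16 for the testis list and 0.12 for the seminal fluid list. Camera called these 12 lists, and the first 3 held with an estimated correlation. The small mean of the digestive list hides opposite directions. Of its 39 genes 7 had a higher and 9 a lower effect in F1 males (11 and 14 adjusted over the list alone). Divided after the values were seen, its 14 carbohydrases had 0 higher and 8 lower effects (median -0.90). Its 22 peptidases had 6 higher and 1 lower (median 0.47).

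Methylphenidate-fed males had 629 calls and sons of exposed mothers 1. Lower sensitivity of the F1 arrays would leave their intervals wide. In a fit of these arrays alone the 95% interval excluded 0.5 times the exposed-male change for 76.8% of the 629 probe sets. The median half-width was 0.203 against 0.226 in exposed males alone. Over all probe sets it was 0.208 against 0.192, so the F1 intervals were the wider ones there. The 629 had passed in a fit whose error included the F1 arrays. That favours narrow F1 intervals and large exposed-male changes among them. Without replicate 3 of the sons of sucrose parents 2 probe sets passed. That fit has fewer arrays and could miss changes for this reason, so it cannot decide about a poorer F1 array. F1 changes smaller than 0.5 times those in exposed males remain open. The values are in line with a response limited to the flies that were fed the drug, which is a hypothesis.

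Methylphenidate-fed males and F1 males of sucrose parents differed from sucrose-fed males in the same direction for 252 higher and 107 lower probe sets. Without replicate 1, 2 or 3 of the sucrose-fed males it was 156, 218 or 168 higher and 41, 67 or 36 lower. These fits had 404, 467 or 398 methylphenidate calls in place of 629, and r was 0.363, 0.450 or 0.400 against 0.381. Simulated draws without effects, with all 3 sucrose-fed arrays shared, gave r of 0.460 to 0.542, above the 0.381. No draws were made for the fits without 1 of these arrays, so their r has no such reference. The share of equal signs, 66.2%, was not above the simulated 66.7% either. Effects present in only 1 of the contrasts can lower r and this share, and the draws hold none, so neither value decides. In simulated draws the spread of the shared sucrose-fed arrays gave a covariance of at most 0.00661, below the 0.0250 measured. Splits of these arrays that left none shared gave 0.0123 to 0.0246. With the GAPDH difference as a covariate, as a measure of the RNA integrity of these arrays, the covariance was 0.0322. Simulated draws with this covariate gave at most 0.0160. Of 203 calls with it, 69 were higher and 23 lower in both. The noise of all these draws was independent between probe sets. Deviations shared by many genes on an array could give a covariance above their highest value, so the draws cannot exclude either explanation. A real difference of the 3 sucrose-fed samples from all others, in feeding or handling for example, was not tested and cannot be told from a response shared by drug and generation.

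For 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real grouping, 1 of the 10, called 629 probe sets in exposed males, 1 in F1 males and 3854 between the sucrose groups, and the highest other split called 0 in each. The correlation of -0.156 between the effects in exposed and F1 males was reached in size by 7 of 100 pairs of splits, so chance is not excluded.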

How the results depend on the processing

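In exposed males, the 12 largest increases and 12 largest decreases named and DAT, ple and Ddc kept their direction and their side of the threshold in all alternatives fixed beforehand; other list members were not followed singly. Counts moved further: 411 with only the groups of the contrast, 1009 with trend and robust settings, 203 with the GAPDH covariate and 398 to 530 without 1 array. All 629 changes kept their direction with the covariate, and their median ratio to the change without it was 0.968. The median SE rose from 0.102 to 0.147. A wider error lowers the count, and whether the lost calls also shrank was not examined. In F1 males 2 passed with the groups of the contrast only and with quantile normalization, 4 with centred arrays, 5 with trend and robust settings, 0 with array weights, 0 under the 50% filter, 1 probe set per gene and the mean of probe sets, which leave out the dim, unnamed probe set called, and 0 to 2 without 1 array. For the difference of effects the count was 616 with trend and robust settings, 209 with the covariate and 241 to 538 without 1 array. Between the sucrose groups it was 2711 to 4006 without 1 array and 2604 with the covariate. The correlation of effects was -0.195 to -0.103 without 1 array (permutation p 0.03 to 0.18). Except where fewer arrays or probe sets entered, the cause was not tested.

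Called lists went from 13 to 3 in exposed males, from 5 to 0 in F1 males, from 12 to 3 for the difference and from 13 to 0 between the sucrose groups with an estimated correlation, and to 7, 0, 7 and 11 with fry, of which 7, 0, 6 and 9 were lists called by camera. In F1 males 3 to 8 lists were called without 1 array. Directions turned only for changes near 0 that never passed: DAT in F1 males (-0.0508 to 0.214 without 1 array, negative without replicate 3 of the sons of sucrose parents), ple in F1 males (-0.0549 centred, -0.00295 with array weights, -0.0409 to 0.0680 without 1 array, negative without that array or, at -0.0341, replicate 1 of the sons of exposed mothers) and Vmat in exposed males (0.0190 as the mean of probe sets). CG13912, CG12780, CG16775, CG42822 and CG15255 passed in F1 males under at least 1 alternative.

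Replicate numbers did not pair the samples (correlation of deviations -0.17 to 0.13). With the replicate number as a block 426 probe sets passed in exposed males, 1 in F1 males, 276 for the difference and 3571 between the sucrose groups, and 13, 5, 12 and 13 lists. Signals near the floor, 36.8% to 38.8% of probe sets, limit what could be measured, and changes of such genes are understated.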

Other observations

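Ecdysteroid kinase-like genes, a family first noticed through CG13659, CG11893 and CG6908, were higher in methylphenidate-fed males. Its 51 members were listed from prior knowledge after the values had been seen, and the test below was chosen then too. Of 45 measured genes 23 rose and 3 fell, for example CG13658 (6.52-fold), CG6830 (5.73-fold) and CG31288 (4.99-fold), with a median log2 change of 0.51. In F1 males none passed in limma, the effect differed between generations for 17 lower and 2 higher genes, and between the sucrose groups 16 were higher and 1 lower. Probes shared between relatives could copy a single response to many genes, but 22 of the 42 genes measured by probe sets without a cross-hybridization suffix rose. That the family responds to the drug as a group is a hypothesis found and tested on the same data.

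Of 80 oxidative phosphorylation genes 24 were higher and 16 lower in F1 males of sucrose parents than in sucrose-fed males (44 and 19 adjusted over the list alone). Camera gave adjusted p = 1.3e-05, and adjusted p = 0.518 with an estimated correlation. Divided after their values were seen, the 23 genes whose name ends in L, or in L and a digit, most of them copies of another subunit gene, held all 16 lower ones, for example COX6AL2 (-0.54), with a median of -0.36. Their 1 higher member was ND-MNLL, whose name is that of the subunit and not of a copy. Of the other 57 genes 23 were higher and none lower, for example COX7A (0.37), with a median of 0.20. None of the 80 passed with methylphenidate in exposed males (camera adjusted p = 0.127).

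Other lists were not called in exposed males. The photoreceptor list lacks 11 of its names, among them ninaE, norpA, Rh2, Rh3, Rh4, Rh5 and Rh6. Of 20 photoreceptor genes ninaB rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.841; median -0.03, mean 0.05, direction up), of 13 clock genes tim rose (2 and 0; 0.118), and of the 115 genes of the cuticle list Cpr67Fb and Cpn, the latter a photoreceptor protein (calphotin) and no cuticle protein, rose (2 and 0; 0.306). Of 52 odorant-binding genes Obp99b fell (0 and 0; 0.841), of 15 glial genes Tret1-1 (0 and 1; 0.688) and of 15 activity-regulated genes cbt (0 and 1; 0.937). None of 27 female-specific genes and of 41 chromatin genes passed by limma (0.774 for each). Between the sucrose groups 3 photoreceptor genes were higher and 9 lower in F1 males, with Arr2 at -0.81 and inaD at -0.79, and DAT was higher by 0.37 ± 0.11 (SE, limma adjusted p = 0.0335).

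The 4 Turandot stress genes were too few for a list test. TotC differed by -0.54 ± 0.53 (SE) with methylphenidate and by 0.22 in F1 males, and TotB, TotF and TotZ lay at the floor; none passed in limma.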
